A study of Mus musculus with 2 samples.

How the data were processed

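ChIP-seq for H3R17me2a was analysed in 2 samples of wild-type mouse heart at 21 days, which form 1 group per the labels. The labels' protocol describes sonicated chromatin from homogenised frozen cardiac tissue and names the antibody's target as H3R17me2, while the series design names H3R17me2a. The labels do not say whether the samples came from separate animals. FastQC, Bowtie2 and the mm10 build are named in the submitters' processing notes, without versions. The peak caller, its version, the control library, the handling of duplicate reads and the filters are not given in the sources used here.

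Each sample has 1 deposited peak list without a header, in the 10-column narrow peak layout. Whether each list was called on the reads of its own sample is not given in the sources used here, and the reads recovered from both lists leave it open. The deposited fold enrichment is a linear ratio of ChIP signal to background at the summit, read from the layout and the values. The deposited p-values and q-values are on a −log10 scale, as the authors' caller wrote them, and the deposited score is 10 times the −log10 p in nearly all peaks (100% in list 1 and 99.997% in list 2). The fold, p and q of a peak are the authors' own values and were used only to describe, rank or filter peaks within a list. The lowest −log10 p was 5.0 in list 1 and 2.01 in list 2, and 38.1% of list 2 peaks had a q above 0.05. The peak numbers of list 1 run to 21512, of which 15 numbers have no peak in the list, and those were not analysed here. List 1 also holds 1 mitochondrial peak, kept out of all tests.

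The reads behind each summit were recovered from the deposited values. If the fold is (reads + 1) / (background + 1) and p the upper Poisson tail of the reads given the background, each fold and p pair fixes a whole number of reads. This reproduced p within 0.001 on the −log10 scale in 99.97% of list 1 peaks. In list 2 it did so in 99.93% of peaks once the ChIP reads were multiplied by 0.618, a factor found by scanning values on peaks with the same summit base in both lists. With p-values exchanged between peaks, 1.1% and 2.9% were matched. On simulated peaks the known reads came back in 100% of 791 peaks without and 698 with the factor. The factor was given in that simulation, so the scan itself was not tested. Differences between lists were set against independent Poisson draws with each pair's mean. The peak names of both lists also carry the same sample number, 3, and the same age of 3 weeks. The analysis was chosen after seeing the data, and because of it the samples are counted as 1 and the lists are treated as 2 peak calls. The recovered background had a median of 4.0 in list 1 and 3.0 in list 2 over overlapping peaks, with Spearman's rho of 0.902 between lists. The list 2 background is on the scale of ChIP reads multiplied by 0.618. The medians are therefore in different units and do not show which list had the higher background.

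Genes came from a RefSeq gene table for GRCm38.p6, whose primary chromosomes have the coordinates of mm10. It gives gene spans without strand, transcript starts or exons, so the promoter, exon and UTR classes that had been planned were not analysed, and the 1000 bp on both sides of each end of a protein-coding gene took the promoter's place. That window can hold a gene's 3′ end or a neighbour's promoter. The 21887 protein-coding genes on chromosomes 1 to 19, X and Y were used. Coordinates are 1-based.

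Overlap meant at least 1 bp (bedtools 2.31.1). Random placement moved each peak within its chromosome, from the first to the last gene or peak, 100 times, and assembly gaps were not excluded. A gene was marked at its end when a peak of each list overlapped the window, and in its body when a shared peak overlapped its span. Gene lists (24, for heart, its cell types, metabolism, arginine methylation and silent families) and the rule for named genes were fixed before the data were examined. The rule took the 15 shared peaks with the lowest summed rank by fold, up to 3 members of each list with the lowest summed rank of their best gene-end peak, up to 2 members without a peak in alphabetical order where fewer than 3 had one, every Prmt gene and the 5 widest shared peaks by the narrower width of each pair. Some genes that the rule selects are not reported here. Gene-end lists were compared with all other protein-coding genes by two-sided Fisher's exact test, and gene-body lists with 10000 random lists matched on gene length in 10 bins, whose smallest p is 0.0002. Benjamini-Hochberg adjustment ran over the 24 lists, and calls were made at an adjusted p under 0.05. For wide peaks matched on fold it ran over fewer lists, those with at least 5 members that had a shared peak nearby. Genes are not replicates, so these p-values compare genes within 1 sample and say nothing of the spread between animals. Intervals are 95% exact binomial, the limit that a count of 0 allows is 3 counts, and both cover counting error only.

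On simulated lists, a planted overlap of 59.3% of 21496 peaks was found as 59.7%. Over 21887 genes, 100% of planted lists were found by both tests, and 2.5% and 2% of null lists had an unadjusted p under 0.05. Alternatives fixed in advance were the upper 50% of each list by fold, list 2 trimmed to the length of list 1, merged or widened peaks, 50% reciprocal overlap, circular shifts, a 3000 bp window, any overlap with the window, a background without receptor families, lists not matched on length and each list alone. Added after seeing the data were a common −log10 p of 5, a common −log10 q of 2, gene ends with no other gene's end within 2000 bp, and gene bodies over 5000 bp with only peaks that touch no gene-end window. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.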

Results

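The series measured where the asymmetric dimethyl mark on an arginine of histone H3, H3R17me2a, lies along the genome of the mouse heart. Chromatin immunoprecipitation followed by sequencing (ChIP-seq) pulls down DNA fragments with an antibody to a histone mark, and a peak is a stretch where those fragments pile up above background. The mark is deposited by Carm1, the arginine methyltransferase and transcriptional coactivator named in the series title, which places the work in cardiac maturation. Both samples fall into 1 group, wild-type heart at 21 days after birth, and no control or other genotype was analysed here. One label of both samples names cardiac fibroblasts, whereas the tissue label and the extraction protocol name whole frozen heart tissue, and the series describes the hearts as neonatal. The sample titles name carm1 although the genotype label is wild type. The protocol names the antibody's target as H3R17me2, and the asymmetric form H3R17me2a comes from the series design. Each sample has its own peak list, called list 1 and list 2 here after the sample numbers in the labels.

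List 1 held 21496 peaks on the autosomes, X and Y, with a median width of 460 bp and 12.9 Mb covered. List 2 held 38012 peaks with a median width of 459 bp and 23.6 Mb covered. The authors' median fold enrichment over background was 4.98 in list 1 and 3.53 in list 2. The lists did not share a threshold, since the weakest peak had a −log10 p of 5.0 in list 1 and 2.01 in list 2, and 51.3% of the list 2 peaks fell below 5. Total read depth is unknown from these lists, but the number of ChIP reads at each peak summit could be recovered from the fold and the p-value. Its median was 26 reads in list 1 and 15 in list 2.

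The recovered reads of the lists were closer to each other than those of independent replicates would be. In 42.3% of 20865 overlapping pairs of peaks the summits fell on the same base, and in 7.80% they were 1 bp apart. The recovered reads of a pair differed by a median of 1 read, against 5 in simulated independent draws of the same depth, and 71.7% of pairs lay within 2 reads against 26.3%. Among the 8823 pairs with the same summit base, Spearman's rho of the reads across peaks was 0.995, and the SD of the difference in units of counting error was 0.303, where independent draws gave 1.00. Over all overlapping pairs that SD was 1.21, raised by pairs with different summits, and its median absolute value was 0.162 against 0.674. The list 2 reads rest on a factor found by presuming equal reads at shared summits, so their closeness to list 1 rests partly on that step. The summit positions were read directly from the lists. With that factor the lists differed by less than the sampling noise at most peaks, and the samples were counted as 1 sample. A value printed for both lists shows how peak calling moved it and carries no replicate error, so no mean and SD over samples are given.

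The peaks of the lists largely coincided. Of the list 1 peaks, 97.1% (20878) overlapped a list 2 peak, and of the list 2 peaks 52.2% (19852) overlapped a list 1 peak. Random placement of the same peaks on their chromosomes gave 1.92% ± 0.0956 and 1.09% ± 0.0540 (SD of 100 placements). Both lists appear to rest on largely the same reads. If they do, an overlap above random placement was set in advance, so it is not taken as a test of agreement between samples. With both lists held to a −log10 p of 5, an alternative chosen after seeing the data, the shares were 72.7% and 79.6%. Across the 20878 shared peaks, which are not independent replicates, Spearman's rho of fold enrichment was 0.606 and Pearson's r of its log2 was 0.607. Peaks of list 1 found in list 2 are the shared peaks below.

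H3R17me2a peaks gathered at the ends of protein-coding genes. The gene table used here gives the span of each gene without its strand, so a gene end is the 1000 bp on either side of either end of that span. Of the shared peaks, 36.9% (7695; 95% exact interval 36.2 to 37.5%) had their midpoint at a gene end, 11.6-fold more than the 3.17% of randomly placed peaks. The excess was 7.13-fold in the upper 50% of peaks by fold, 5.44-fold with a 3000 bp window and 7.86-fold for all list 2 peaks. A further 44.3% lay elsewhere inside protein-coding genes (1.14-fold), 4.79% in other annotated genes (0.591-fold) and 14% between genes (0.282-fold), each class with a two-sided permutation p of 0.0198, the smallest that 100 placements can give. The gene-end share was 36.6% of all list 1 peaks and 25% of all list 2 peaks, and 35.9% of list 2 peaks with a −log10 p of at least 5. The excess inside genes lost its call with both lists at that threshold (1.02-fold, permutation p = 0.0792).

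**Figure D1:**
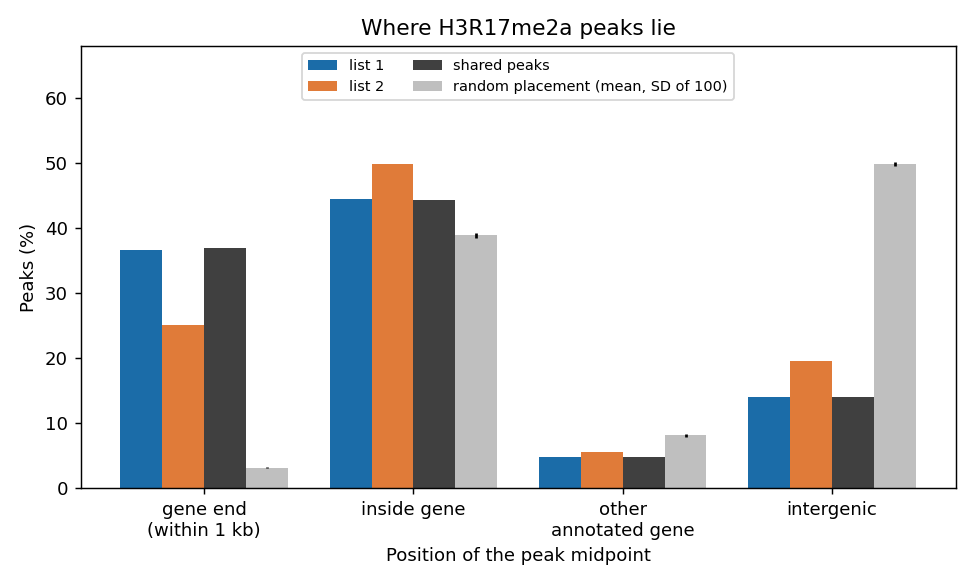
Share of peaks (%, vertical axis) whose midpoint lies at a protein-coding gene end, elsewhere inside such a gene, in another annotated gene or between genes (horizontal axis), for list 1, list 2, the shared peaks and random placement (mean, error bar SD of 100 placements). The shared peaks reach 36.9% at gene ends against 3.17% by random placement, and 14% between genes against 49.8%.

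A gene-end peak in both lists marked 8455 of 21887 protein-coding genes (38.6%). In 8441 of them a gene-end peak of list 1 overlapped one of list 2, and in 14 none did. List 1 alone marked 8575 genes and list 2 alone 10106. Among marked genes longer than 5000 bp, 6931 carried the mark at 1 end and 453 at both, so that 93.9% were marked at a single end. A shared peak overlapped the body of 9410 genes (43.0%). Restricting both lists to the upper 50% of their peaks by fold lowered the genes marked at an end to 2692.

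Structural and contractile genes of the cardiomyocyte were among the most frequently marked. Of 24 adult sarcomere genes, 22 had a gene-end peak in both lists, against 38.6% of the other genes (two-sided Fisher's exact test with Benjamini-Hochberg adjustment over 24 lists, adjusted p = 3.5e-07). The folds given for a gene are those of its strongest gene-end peak in each list, and at Myom2, Pfkm, Ucp3, Myocd and Cd68 these strongest peaks did not overlap each other. Actc1, the cardiac alpha actin (mm10 chromosome 2, 114047282 to 114052875), had fold enrichments of 15.5 in list 1 and 10.1 in list 2 from peaks of 3173 and 3156 bp that began at the same base, 114045249. At Tnni3, cardiac troponin I (chromosome 7, 4518305 to 4522718), the folds were 16.0 and 8.73, but the list 1 peak (4513289 to 4517552) overlapped the neighbouring troponin gene Tnnt1 and ended before Tnni3, whereas the list 2 peak (4513128 to 4519381) overlapped both. Myom2, a component of the sarcomere's M-band (chromosome 8, 15057653 to 15133420), had folds of 13.1 (15058389 to 15059295) and 9.04 (15057053 to 15058136). The sarcomere genes without such a peak, named after their values were seen, were Neb and Nebl.

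Genes of calcium handling and electrical conduction carried the mark as well. Gene-end peaks were found at 16 of 20 calcium handling genes (Fisher's adjusted p = 0.00051). Casq2, the calcium-binding protein of the cardiac sarcoplasmic reticulum, had folds of 9.67 and 9.35, Trdn, its membrane partner triadin, 6.94 and 11.5, and Pln, the calcium pump inhibitor phospholamban, 8.34 and 7.10. Of 22 ion channel and conduction genes, 14 were marked (Fisher's adjusted p = 0.0296), with folds of 6.0 and 7.74 at the potassium channel subunit Kcne1 and 8.34 and 5.39 at Abcc9, a subunit of the ATP-sensitive potassium channel. The ion channel call was lost under 5 of 9 alternatives, among them list 2 alone (Fisher's adjusted p = 0.0597) and both lists at a −log10 p of 5 (0.121), and its adjusted p ranged from 0.0081 to 0.156. The calcium handling call held under all 9 (2.2e-05 to 0.0021).

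Genes of energy metabolism were marked more often than the other genes in all 3 lists tested. Of 36 genes of oxidative phosphorylation and the tricarboxylic acid cycle, 35 had a gene-end peak in both lists (97.2%, Fisher's adjusted p = 4.5e-13), and the exception, named after its value was seen, was Cox5a. Mitochondrial malate dehydrogenase Mdh2 had folds of 6.71 and 12.1, and the respiratory chain cytochrome gene Cyc1 7.80 and 6.90. Fatty acid oxidation followed with 23 of 27 genes (Fisher's adjusted p = 3.0e-06), led by Etfdh, which passes electrons from fatty acid oxidation to the respiratory chain (11.8 and 11.0), Decr1, an enzyme for unsaturated fatty acids (8.64 and 6.31), and Ucp3, a mitochondrial uncoupling protein of muscle (6.67 and 6.50). Glycolysis had 16 of 21 genes (Fisher's adjusted p = 0.00090), among them muscle phosphofructokinase Pfkm (12.9 and 8.55), the insulin-responsive glucose transporter Slc2a4 (9.38 and 6.83) and Gpi1 (8.58 and 5.57). Both ends of Etfdh lie within 2000 bp of another gene's end, and the Mdh2 peak is at such an end too, so these peaks cannot be assigned to 1 gene. All 3 list calls held under 9 alternatives.

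Regulators of that metabolism and of cardiac identity were marked too. Of 28 metabolic maturation regulators, 21 had a gene-end peak in both lists (Fisher's adjusted p = 0.00027). Esrra, a nuclear receptor that drives mitochondrial genes, had folds of 8.72 and 9.48, the thyroid hormone receptor Thrb 8.82 and 5.88, and Ppargc1a, the coactivator of mitochondrial biogenesis, 7.80 and 5.02, where the Esrra and Thrb peaks lie at ends shared with another gene. Among cardiac transcription factors, 19 of 24 were marked (Fisher's adjusted p = 0.00017), with Tbx20 at 9.53 and 6.77, Gata6 at 7.05 and 6.55, and the cofactor Myocd at 5.47 and 5.32 from opposite ends of the gene. Coactivators and chromatin factors had 18 of 24 genes marked (Fisher's adjusted p = 0.00078), including the Mediator subunit gene Med12 (5.97 and 5.36), the histone methyltransferase gene Kmt2d (4.15 and 7.21, at an end shared with another gene) and Ctcf (6.30 and 3.8). In the upper 50% of peaks by fold the calls for cardiac transcription factors (Fisher's adjusted p = 0.153, range over alternatives 1.1e-06 to 0.153) and coactivators (1.0, range 6.6e-06 to 1.0) were lost. The coactivator call was also lost with list 2 trimmed to the length of list 1 (0.128). Kmt2d had no gene-end peak in both lists in the upper 50% of peaks by fold.

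Genes used in many cell types were marked as well. All 27 autophagy and lysosome genes had a gene-end peak in both lists (Fisher's adjusted p = 3.3e-11), with folds of 10.2 and 6.91 at the autophagy receptor Sqstm1, 9.13 and 5.44 at Gabarap, whose ends lie near another gene's, and 5.67 and 10.8 at Atg16l1. Ribosomal protein genes were marked at 71 of 83 (Fisher's adjusted p = 1.0e-17), led by Rpl10 (10.5 and 10.3) and Rpl6 (11.4 and 8.02). Zinc finger genes with Zfp symbols were marked at 197 of 394 (Fisher's adjusted p = 1.1e-05), with Zfp619 at 12.4 and 10.8, Zfp27 at 11.5 and 10.6 from an end shared with another gene, and Zfp157 at 10.4 and 11.8. Cell cycle genes were marked at 19 of 32 (Fisher's adjusted p = 0.0220), among them E2f2 (6.85 and 5.28), the cyclin gene Ccne1 (5.88 and 4.80) and Mcm2, a subunit of the replication helicase (4.06 and 6.59). The cell cycle call was lost under 5 of 9 alternatives, with an adjusted p of 0.0659 at a common −log10 p of 5 and a range of 0.00045 to 0.506. Its direction turned in the upper 50% of peaks, where Mcm2 had no gene-end peak in both lists.

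The arginine methylation machinery itself was marked at 12 of 17 genes (Fisher's adjusted p = 0.0133). Carm1 (chromosome 9, 21546894 to 21589467) had folds of 4.33 and 2.86, from an end that lies within 2000 bp of another gene's end, as do both ends of Prmt7. Prmt1, the main asymmetric arginine methyltransferase, had 2.59 and 4.26, and Prmt5, the main symmetric one, 3.53 and 3.79. Folds were 5.36 and 3.54 at Prmt2, 4.12 and 3.36 at Prmt3, 4.86 and 3.54 at Prmt7, 4.41 and 2.56 at Prmt8 and 4.0 and 6.84 at Prmt9, whereas Prmt6 had a peak in list 1 alone (4.20). Clns1a, a cofactor of Prmt5, had 3.22 and 9.47. The call was lost with list 2 alone (Fisher's adjusted p = 0.0597) and at a common −log10 q of 2 (0.0503), and its direction turned in the upper 50% of peaks by fold (0.777), with a range of 0.0030 to 0.777 over alternatives. In that setting Carm1, Prmt1, Prmt3, Prmt5, Prmt7, Prmt8, Prmt9 and Clns1a had no gene-end peak in both lists. Carm1 and Prmt8 had none when list 2 was trimmed to the length of list 1, nor Prmt2 and Prmt8 at a common −log10 p of 5 or q of 2.

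**Figure D2:**
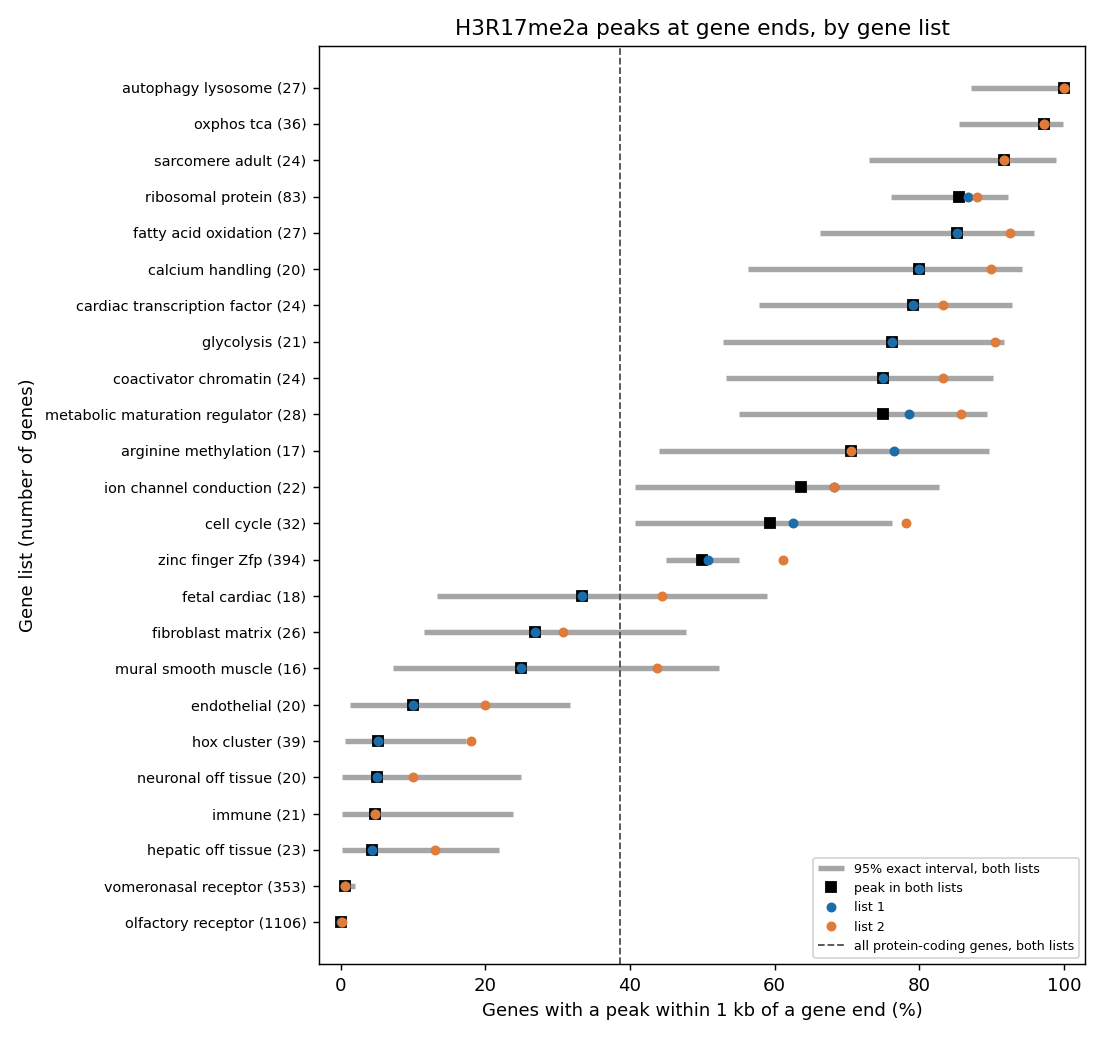
Share of genes with a peak within 1 kb of a gene end (%, horizontal axis) for the 24 gene lists (vertical axis, number of genes in parentheses), in list 1, in list 2 and in both lists, with 95% exact intervals that cover counting error only and a dashed line at the 38.6% of all protein-coding genes. Autophagy, oxidative phosphorylation and sarcomere genes sit above 90%, and the receptor families sit at 0.567% and 0%.

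Marker genes of other cell types and tissues were marked rarely. Endothelial genes had gene-end peaks in both lists at 2 of 20 (Fisher's adjusted p = 0.0127), the nitric oxide synthase gene Nos3 (4.07 and 3.56) and the adhesion gene Esam (4.47 and 3.39), both at ends near another gene, while Cd34 and Cdh5 had none. Immune genes were marked at 1 of 21 (Fisher's adjusted p = 0.0014), the macrophage gene Cd68 (3.75 and 3.37, again near another gene's end), with none at Adgre1 and C1qa. Neuronal genes were marked at 1 of 20 (Fisher's adjusted p = 0.0014), the glutamate transporter gene Slc17a7 (5.64 and 4.25), with none at Gad1 and Gad2. Hepatic genes were marked at 1 of 23 (Fisher's adjusted p = 0.00061), the apolipoprotein gene Apoa2 (3.36 and 4.78, near another gene's end), with none at Ahsg and Alb. Hox cluster genes were marked at 2 of 39 (Fisher's adjusted p = 8.9e-06), Hoxd3 (6.12 and 3.71) and Hoxc5 (3.20 and 2.05), with none at Hoxa10. Vomeronasal receptors were marked at 2 of 353 (Fisher's adjusted p = 9.8e-71), Vmn1r4 (6.33 and 4.65, near another gene's end) and Vmn2r3 (4.33 and 2.81), with none at Vmn1r1 and Vmn1r10. No olfactory receptor of 1106, Olfr1 and Olfr10 included, was marked in both lists (Fisher's adjusted p = 1.4e-241; a count of 0 allows a share of up to 0.271%, taken as 3 counts, and the 95% exact interval reaches 0.333%). In the upper 50% of peaks by fold the endothelial (Fisher's adjusted p = 0.216, range over alternatives 0.0033 to 0.216), hepatic (0.153, range 0.00014 to 0.153), Hox (0.141, range 9.2e-07 to 0.141), immune (0.153, range 0.00014 to 0.153) and neuronal (0.573, range 0.00056 to 0.573) calls were lost. The endothelial (0.156), immune (0.0566) and neuronal (0.0566) calls were also lost with list 2 trimmed to the length of list 1. At a common −log10 p of 5, Esam, Cd68, Hoxd3, Hoxc5 and Vmn2r3 had no gene-end peak in both lists. That left 1 of 20 endothelial, 0 of 21 immune and 0 of 39 Hox genes marked. In the upper 50% of peaks by fold, Nos3, Esam, Cd68, Apoa2, Hoxc5 and Vmn2r3 had none.

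Fibroblast, mural and fetal cardiac genes were not called apart from the other genes. Fibroblast and matrix genes had gene-end peaks at 7 of 26 (Fisher's adjusted p = 0.327), with folds of 9.45 and 7.20 at Tgfb1, 4.94 and 4.46 at Vim and 4.79 and 3.49 at Sparc. With both lists at a −log10 p of 5 the share was 11.5%, below the other genes (Fisher's adjusted p = 0.0257; range over alternatives 0.0257 to 0.457), and the Sparc peak was no longer in both lists. Mural and smooth muscle genes had 4 of 16 (Fisher's adjusted p = 0.327), among them Abcc9, Acta2 (7.34 and 4.66) and the intermediate filament gene Des (4.20 and 7.74), of which Des is also a sarcomere gene. Fetal cardiac genes had 6 of 18 (Fisher's adjusted p = 0.810), among them the pyruvate kinase gene Pkm (6.84 and 6.28), the stress-responsive Ankrd1 (5.59 and 6.90) and Acta2. The fetal list was above the other genes in the upper 50% of peaks by fold (Fisher's adjusted p = 0.0317; range over alternatives 0.0317 to 1.0). In that setting Vim, Sparc and Des had no gene-end peak in both lists.

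Peaks over gene bodies were counted next, and most of them repeat the gene ends, since 7944 of the 9410 genes with a body peak (84.4%) were also marked at an end. Against 10000 random lists of the same gene lengths, 14 lists carried shared body peaks more often, 6 less often and 4 were not called (two-sided permutation test, Benjamini-Hochberg over 24 lists). Sarcomere genes had a body peak at 23 of 24 against a random mean of 47.7% (adjusted permutation p = 0.00044), fatty acid oxidation genes at 26 of 27 against 48.8% (0.00044) and ribosomal protein genes at 75 of 83 against 29.5% (0.00044). Hox genes had 1 of 39 against 35% (adjusted permutation p = 0.00044), which was Hoxc5, and immune genes 1 of 21 against 40.4% (0.00080), which was Spi1, both named after their values were seen. Endothelial (25% against 48.5%, adjusted permutation p = 0.0574), fibroblast (8 of 26 against 51%, 0.0574), fetal cardiac (9 of 18 against 38.9%, 0.460) and mural genes (8 of 16 against 49.2%, 1.0) were not called. With list 1 alone the endothelial and fibroblast lists were called lower (adjusted permutation p = 0.0493 for both), and the endothelial list also at a common −log10 q of 2 (0.0403), with ranges over alternatives of 0.0403 to 0.752 and 0.0493 to 0.797. In the upper 50% of peaks by fold the body calls were lost for immune (adjusted permutation p = 0.0617, range 0.00037 to 0.0617), hepatic (0.251, range 0.00080 to 0.251), neuronal (0.343, range 0.00037 to 0.343), coactivator (0.382, range 0.00032 to 0.382) and Zfp genes (0.136, range 0.00032 to 0.136), and for arginine methylation (1.0, range 0.00032 to 1.0) and cell cycle genes (1.0, range 0.00048 to 1.0), whose direction turned. The arginine methylation call was also lost at a common −log10 q of 2 (adjusted permutation p = 0.0603), and the calcium handling call with list 2 alone (0.090, range 0.00080 to 0.090).

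Away from every gene end, several lists of heart muscle and metabolism genes carried the mark inside the gene more often. In this test, added after seeing the data, only shared peaks that touch no gene-end window (12679) and genes over 5000 bp were used, and 8 lists were higher than length-matched random lists, 2 lower and 14 not called. Sarcomere genes had such a peak at 18 of 21 against a random mean of 22% (adjusted permutation p = 0.00080), cardiac transcription factors at 18 of 22 against 26.5% (0.00080), ion channel and conduction genes at 15 of 20 against 23.5% (0.00080) and metabolic maturation regulators at 19 of 28 against 25.9% (0.00080). Fatty acid oxidation (15 of 27 against 15.1%, adjusted permutation p = 0.00080), glycolysis (10 of 18 against 16%, 0.0014), calcium handling (12 of 17 against 30.4%, 0.0024) and fetal cardiac genes (6 of 13 against 16.2%, 0.0298) were also higher. Olfactory (0 of 74, 95% exact interval to 4.86%, against 8.35%, adjusted permutation p = 0.0096) and vomeronasal receptors (0 of 133, to 2.74%, against 14.8%, 0.00080) were lower. Of the lists called with all body peaks, oxidative phosphorylation (8 of 30 against 11.7%, adjusted permutation p = 0.0860), ribosomal protein (3 of 14 against 6.38%, 0.189), autophagy (8 of 25 against 18.5%, 0.211), coactivator (0.134), arginine methylation (1.0), cell cycle (0.875), Zfp (0.771), Hox (0.617), immune (0.771), hepatic (0.861) and neuronal genes (0.211) were not called.

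The peaks with the highest fold enrichment lay mostly away from gene ends. Of the 15 strongest shared peaks by summed rank, 1 was within 1 kb of a gene end, that of Eif2s3y, a translation initiation factor gene on the Y chromosome (1009484 to 1010707; folds 23.7 and 27.7). The first by rank lay inside Sspn, the gene of the dystrophin-associated protein sarcospan (chromosome 6, 145940913 to 145941266; 27.3 and 27.7). The next lay 16733 bp from Gadl1 (chromosome 9, 115867381 to 115867938; 44.1 and 25.5), and a further peak lay 12192 bp from Vegfa, the angiogenic growth factor gene (chromosome 17, 46003910 to 46004801; 21 and 24.1). Others overlapped Emilin2 (30.9 and 21.6), Shisal1 (35.3 and 21), Homer1 (27.4 and 20.4), Zfp608 (22.7 and 20.6) and Srpk2 (23.3 and 19.3). The rest overlapped no protein-coding gene, and their nearest was Zfp385b at 8121 bp (19.4 and 32.1), Arid1b at 19117 bp (22.7 and 25.2), Dyrk2 at 55284 bp (30.7 and 19), Zfp536 at 63263 bp (24.4 and 25.9) or Tox3 at 232902 bp (21.1 and 21.9).

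The 5 widest shared peaks were ranked by the narrower width of each pair. The first, 18422 bp in list 1 and 27393 bp in list 2, overlapped Neat1, the RNA scaffold of nuclear paraspeckles (chromosome 19, 5817886 to 5836307 in list 1; folds 7.32 and 4.35). The second, 14196 and 14239 bp, lay over the end of Wasl on chromosome 6 (24605826 to 24620021). The third, 11290 and 11250 bp on chromosome 2 (180395386 to 180406675), covered the muscle microRNA gene Mir133a-2 and overlapped part of its host transcript Mir1a-1hg. The fourth, 20063 and 10643 bp on chromosome 14 (54934694 to 54954756 in list 1), was wider than the first in list 1 and ran across Il25 and Cmtm5 into Myh6, the adult alpha myosin heavy chain gene, and in list 1 its microRNA Mir208a. The fifth, 8300 and 10289 bp on chromosome 15 (77008744 to 77017043), overlapped Mb, the myoglobin gene (folds 8.55 and 4.93). From 54928694 to 55016626 on chromosome 14, the Myh6 and Myh7 region held 24 peaks covering 59638 bp in list 1 and 26 peaks covering 62563 bp in list 2.

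**Figure D3:**
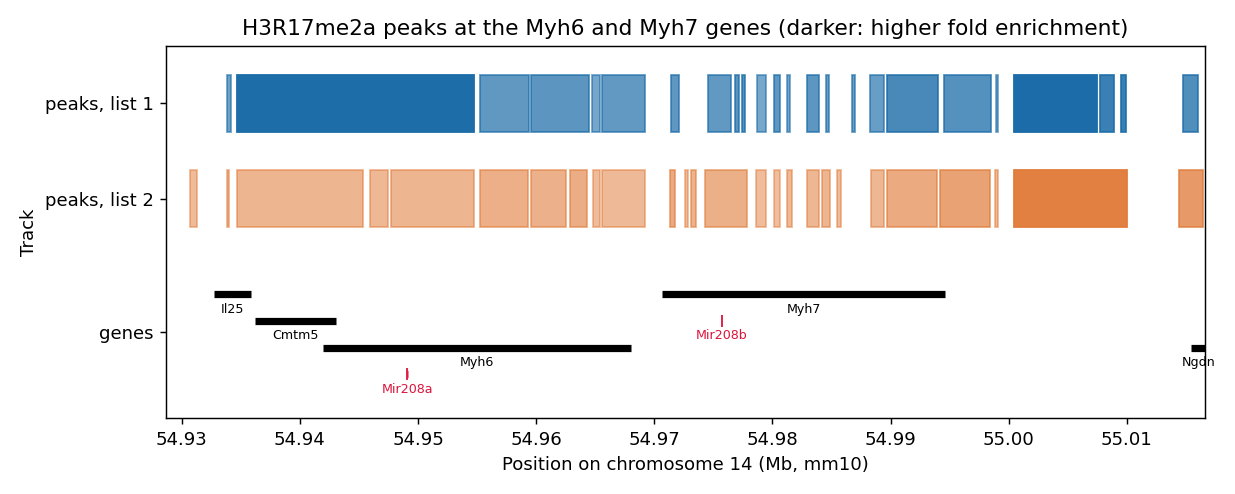
Peaks of list 1 and list 2 (boxes to scale, darker with higher fold enrichment) above the protein-coding genes (black) and microRNA genes (red) of the Myh6 and Myh7 region, by position on chromosome 14 (horizontal axis, Mb, mm10). Peaks cover 59638 bp in list 1 and 62563 bp in list 2, with folds from 3.22 to 10.4 and from 1.91 to 8.57.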

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

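The common −log10 p, the common −log10 q, the gene ends away from other genes, the peaks away from gene ends and the alternatives for wide peaks were chosen after seeing the data. No paired analysis was possible because there is only 1 group, and depth could not be varied because total reads are unknown. The excess at gene ends held under every alternative run, from 5.44-fold (3000 bp window) to 12.9-fold (common −log10 p) over random placement, and sarcomere genes with a wide peak numbered 16 to 19. Of the 24 lists, 11 kept their call and direction under every alternative at gene ends and 13 over gene bodies, except with only peaks away from gene ends, where 12 of 24 had the same call. Over single lists and named genes, 826 comparisons with an alternative were unchanged and 39 gained or lost a peak. Of the 360 for lists, 33 lost a call and 5 gained one, and 15 turned direction, of which 4 also lost a call, 1 gained one and 10 were called neither way. The causes of the changes below were not tested, except that fewer peaks leave fewer marked genes.

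The upper 50% of each list by fold left 10748 and 19006 peaks, 2692 genes marked in both lists, 2 lists below the other genes at gene ends and 3 over gene bodies, and a rho of fold of 0.579. In it the log2 odds ratio at gene ends turned to -0.63 for arginine methylation, -0.78 for cell cycle, 1.89 for fetal cardiac and 0.30 for mural genes, and over gene bodies arginine methylation lay at -3.70 and cell cycle at -0.23 percentage points from random lists. List 2 trimmed to the length of list 1 gave 5540 marked genes, 4 lists below at gene ends and a fetal log2 odds ratio of 0.62. Reciprocal overlap of 50% gave a rho of 0.655 and peak width in place of fold 0.659. The 3000 bp window gave a fetal log2 odds ratio of 0.41 and a mural one of 0.073, and isolated gene ends a fetal one of 0.41.

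At the common −log10 p list 2 held 18502 peaks, the fold over random inside genes was 1.02, rho 0.621, the fetal log2 odds ratio 0.080 and mural gene bodies -12.5 points. At the common −log10 q list 2 held 19876 peaks, with rho 0.618, a fetal log2 odds ratio of 0.011 and mural gene bodies at -13.7 points. With each list alone, mural gene bodies ranged from -5.24 to 0.155 points.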

Other observations

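Of the tests in this part, those on gene length, on the looser threshold and on chromatin from fibroblasts, the tiers of strong and wide peaks, the noncoding genes and the X chromosome were chosen after the results they concern were seen.

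A few microRNA genes, picked by hand, were looked up without a test between tissues. Both lists had a peak within 1 kb of Mir1a-1 (folds 7.0 and 8.51), Mir1a-2 and Mir133a-1 (8.19 and 5.52 for both, from the same peaks), Mir133a-2 (4.03 and 3.88), Mir208a (8.97 and 2.95), Mir208b (4.82 and 3.42), which lie in the Myh6 and Myh7 region, and Mir499 (8.0 and 4.89). Neither list had one at Mir206 and Mir133b, the skeletal muscle pair, at Mir122 of liver, Mir124a-1 of neurons, Mir223 of myeloid cells or Mir126a of endothelium, nor at Mir21a, and Mir9-1 had one in list 2 alone. Among long noncoding genes, Malat1 (5.60 and 6.71), Neat1 and the Myh7 antisense gene Mhrt (5.0 and 3.93) carried peaks, and the fetal H19 did not. A shared peak lay within 1 kb of 10.2% of 1228 microRNA genes, 17.8% of 12727 long noncoding genes, 46.1% of 408 tRNA genes and 1.07% of 9944 pseudogenes.

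The shared peaks with the highest fold lay at gene ends less often than the others. Strength here means the summed rank by fold over background, and peaks were not ranked by p or reads. Such orders can differ, since 13 of the 20 most significant list 1 peaks lay in a region with a median fold of 2.52. Of the strongest 1% (208), 7.21% had their midpoint at a gene end against 37.2% of the others (Fisher's exact test, p = 2.5e-23), and 7.69% against 39.6% overlapped a gene-end window (p = 2.7e-25). For the widest 1% (208, at least 2391 bp) the direction depended on the measure, with 29.3% against 36.9% by midpoint (Fisher's exact p = 0.0250) and 53.4% against 39.1% by overlap (p = 4.3e-05), which a wider peak reaches more easily. The sets had 3 peaks in common, where chance would give 2.07.

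Wide shared peaks were concentrated at sarcomere genes: 17 of 24 carried one of the widest 1%, against 174 of 21887 protein-coding genes (0.795%). They included Ttn, Myh6, Actc1, Myl2, Mybpc3, Actn2, Tpm1 and Ldb3, and wide peaks were also above length-matched random lists at metabolic maturation regulators (Perm1, Ppargc1a, Ppargc1b and Nr3c1; 4 of 28, adjusted permutation p = 0.0120) and cardiac transcription factors (Foxp1, Gata6 and Hand2; 3 of 24, adjusted p = 0.0288). Against lists matched on the fold of the strongest peak neither was called (adjusted permutation p = 0.0558 and 0.312), and 0 of 36 genes of oxidative phosphorylation and the tricarboxylic acid cycle carried a wide peak. The sarcomere excess was 69.86 points over length-matched lists (adjusted permutation p = 0.0048) and 70.68 points over lists matched on the fold of the strongest peak (adjusted p = 0.0036), and 0% of ribosomal protein genes carried a wide peak (Fisher's exact test against sarcomere genes, p = 1.5e-14). These values argue against gene length, peak strength by fold and steady high use in every cell type as the whole cause. What else sets the width stays open; no expression data were used here and no biological explanation was tested.

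List 2 peaks without a list 1 peak numbered 18160, although both lists appear to rest on largely the same ChIP reads. Of these, 79.2% had a −log10 p below 5, against 25.8% of the 19852 matched ones, so the looser threshold of list 2 is a likely source of most of them. It cannot account for the 3777 unmatched peaks past that threshold, 20.41% of 18502. Their median width was 395 bp against 760 bp for matched ones, at median folds of 4.70 and 4.76. The unmatched peaks include 8 with folds of 45.1 to 131 and a −log10 p of 182 to 460, above the list 1 maximum fold of 44.1. Whether the lists share reads at these 8 sites was not tested. List 1 also lacks 15 of its peak numbers, and a link between the gaps and the unmatched peaks was not tested. A different background or read filter in the peak calls stays open, and no biological explanation was tested.

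Sarcomere genes carried gene-end peaks and most fibroblast genes did not, although one label names cardiac fibroblasts. The difference was 64.74 points (22 of 24 against 7 of 26, Fisher's exact test, p = 3.0e-06). These counts prompted the question, so the test restates them and is no separate check. They go against chromatin mainly from fibroblasts only in so far as the mark follows the genes a cell uses, which was not tested. With only peaks over 1000 bp from every gene end, and genes over 5000 bp, the difference was 69.71 points (18 of 21 against 4 of 25, Fisher's exact p = 3.6e-06). That argues against the class of promoter at the gene ends as the whole cause. Promoters inside a gene were not removed, since the gene table has no transcript starts, so their part was not tested. Whole heart tissue, as the tissue label and protocol state, may account for the pattern, and the share of fibroblast chromatin stays open. No biological explanation was tested, since there is 1 group.

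On the X chromosome 17.6% of 966 genes were marked in both lists (95% exact interval 15.2 to 20.1%), against 40.1% of 20665 autosomal genes (Fisher's exact test, p = 3.6e-49), and X held 1.63 shared peaks per Mb against 6.11 to 14.4 on the autosomes. The lists also held 11 and 77 peaks on the Y chromosome, and the number of X copies was not accounted for in this comparison. List 2 held 8 peaks with folds of 45.1 to 131, above the list 1 maximum of 44.1, all 218 to 654 bp wide and none shared. A region of chromosome 6 (47654881 to 47763678) held 14 and 15 peaks about 4336 bp apart with median folds of 2.52 and 3.23, and 13 and 10 of the 20 most significant peaks of list 1 and list 2. The mitochondrial peak of list 1 (15764 to 16004) had a fold of 1.53.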
